A study of Mus musculus with 2 samples.

How the data were processed

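DNase-seq was carried out by the submitters on forebrain tissue of mouse embryos at embryonic day 14.5, pooled over both sexes, per the labels. Both samples form 1 group with 2 biological replicates, numbered as in the labels. They are separate biosamples with 1 shared donor record, and the labels do not say that they came from separate litters, so any spread between them is the spread between these 2 libraries, which may be technical. The labels name sequencing instruments (HiSeq 2500 and NextSeq 500) for replicate 2 only, so a sequencing batch and the replicate cannot be told apart.

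The authors deposited 2 interval sets per replicate, made separately for each replicate from its filtered alignments to mouse assembly mm10, per the text lists deposited with the samples. The aligner, the peak caller, their versions and thresholds and the read numbers are not given in the sources used here. In the deposited peak files each peak is 150 bp wide and carries a signal value, a whole number from 1 to at most 150 in replicate 1 and 147 in replicate 2. No scaling of this signal to library depth is stated in the deposited lists, and its exact definition is not given in the sources used here. No value exceeded the peak width in bp, so differences between strong peaks may be compressed. It is the authors' value per peak and was used to describe and rank peaks within a replicate and to give their correlation and ratio across shared peaks. In the deposited hotspot files each region carries a −log10 q-value of at least 1.30, set to 100 for the most significant regions (40.7% of hotspots in replicate 1 and 30.0% in replicate 2). A display score deposited by the authors, which follows the −log10 q-value, was not used.

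Replicate 1 had 260658 deposited peaks and 225063 hotspots, and replicate 2 had 188205 peaks and 161782 hotspots. Peaks with duplicate coordinates (29 and 44) were counted once, and peaks off chromosomes 1 to 19, X and Y (208 and 188) were left out. Gene models were taken from GENCODE release M21 and sequence from GRCm38.p6, the same assembly as mm10, and no interval ran past the end of a chromosome. Comparisons used bedtools 2.31.1, samtools 1.23.1, pysam 0.24.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Coordinates are 1-based.

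A peak was shared when it overlapped a peak of the other replicate by at least 1 bp. The chance level came from 100 random circular shifts of 1 peak set within each chromosome, past the first 3 Mb. Shared peaks were represented by the peak of replicate 1. Each peak was assigned to the first class it overlapped among promoter (1000 bp either side of any TSS of a protein-coding gene), exon, intron and intergenic, and peaks outside promoters were called distal. Shares of peaks carry Wilson and shares of genes exact (Clopper-Pearson) 95% intervals, which cover counting error only, since neighbouring peaks and genes are not independent.

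The gene lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from those stated below to be chosen later. The 18 lists were forebrain patterning factors, radial glia and progenitors, cortical progenitors and glutamatergic neurons, ganglionic eminence and GABAergic neurons, diencephalon, pan-neuronal genes, the astrocyte and oligodendrocyte lineage, choroid plexus, endothelium and pericytes, microglia and leukocytes, erythroid genes, meninges and mesenchyme, Hox genes, hepatocytes, muscle, housekeeping genes, olfactory receptors and vomeronasal receptors. The erythroid gene Ahsp was not matched in the annotation, which left 15 of that list. For promoters, a gene counted as open if a peak of each replicate overlapped its promoter, and each list was compared with all other protein-coding genes of 21938 by Fisher's exact test, two-sided. For distal peaks, the mean number of shared distal peaks in the DNA nearer to any TSS of a gene than to those of other genes, up to 100 kb on each side of each TSS, was compared with 100000 random lists of the same size, matched on the decile of the length of that DNA, in a two-sided permutation test. Benjamini-Hochberg adjustment ran over the 18 lists, with a threshold of 0.05. The text names, for each list, the pair of genes with the most shared distal peaks and the first pair in alphabetical order with no promoter peak in either replicate, the 10 genes with the most shared distal peaks, the genes nearest to the 10 strongest shared peaks, and the 4 Dlx genes.

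Consensus sequences of 21 motifs were searched on both strands, of which 20 are listed: CTCF (CCASNAGRKGGC), NFI (TTGGCNNNNNGCCAA), RFX (GTTRCYNNRGYAAC), NEUROD/NEUROG (RCAGATGG), LHX/DLX (YTAATTAR), SOX (CCATTGTT), POU (ATGCAAAT), T-box (TCACACCT), MEF2 (YTAWWWWTAR), AP-1 (TGASTCA), TEAD (RCATTCCW), SP/KLF (GGGGCGGGGC), NRF1 (GCGCATGCGC), NFY (RRCCAATSR), ETS (CCGGAAGTG), YY1 (AAGATGGCGGC), GATA (AGATAASR), HNF1 (GTTAATNATTAAC), HNF4 (CAAAGTCCA) and PU.1 (GAGGAAGT). The share of shared peaks with a match was set against windows of the same width centred 1000 bp away on each side and outside every hotspot, as an odds ratio with its 95% interval and Fisher's exact test, two-sided, adjusted over the 21 motifs, for distal and promoter peaks separately. A consensus match is not evidence of binding. Of the motifs searched and the genes that the naming rule selects, 1 motif and some genes are not reported here. Peak density in the Hox clusters and Dlx loci was counted per 100 kb between the outermost gene bounds, and no test was made between the replicates.

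Alternatives were promoter windows of 500 and 2500 bp, TSSs of all annotated genes, distances up to 50 and 500 kb, 1 TSS per gene (its 5' end; chosen after seeing the data), random lists not matched on length, an overlap of 50% of both peaks, equal numbers of peaks, the upper 50% of peaks by signal, autosomes only, hotspots in place of peaks, flanks matched on GC content in bins of 5 percentage points, sequences shuffled with their dinucleotides kept, and each replicate left out in turn. Leaving out each replicate for the genomic distribution and the loci was chosen after seeing the data.

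The steps were tested on simulated data. For distal peaks, with 20 genes per list and 21938 genes, 0 of 100 unchanged lists were called, 5 of 10 lists with a 2-fold change, 7 of 10 with a 3-fold change and 10 of 10 with a 5-fold change. For promoters, 9 of 10 lists set at 25%, 1 of 100 lists at the genome share of 68.5% and 10 of 10 lists at 100% were called. These calls were made after adjustment, among simulated lists that were mostly unchanged. The gene lists tested here were fewer and differed in size. The simulated rates therefore do not give the rates at which changes in those gene lists would be called. All 2000 planted sites were found for each of the 21 motifs, and 0 of 1500 simulated intervals differed from a pairwise comparison of overlaps.

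For the closing observations, 3 further lists were written after the Hox clusters had been seen to differ: limb bud mesenchyme (18 genes, without Hox genes and Tbx5), hindbrain and spinal cord (20 genes, without Hox genes) and craniofacial mesenchyme (10 genes). The lean of a list to a replicate was the log2 ratio of its distal peaks of replicate 2 only to those of replicate 1 only, each divided by the total of that kind within 100 kb of genes (38450 and 78045), with 0.5 added to counts. It was placed among 10000 random lists matched on length decile, among lists also matched on CpG islands within 50 kb (drawn from the 50 nearest genes in island cover), and among lists from 257 genes of developmental transcription factor families chosen by symbol. The 53 genes of the 5 lists of forebrain regions and progenitors that belong to these families were also placed among 10000 random lists from the other 204. CpG islands were windows of 200 bp with at least 50% GC and an observed to expected CpG ratio of 0.6, merged to at least 300 bp. Loci were placed among windows of 100 kb with at least 20 peaks over both replicates, also among those within 2 percentage points of GC content.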

Results

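Chromatin accessibility was mapped by DNase-seq, in which the enzyme DNase I cuts DNA that is not packed into nucleosomes, in forebrain tissue of strain B6NCrl mouse embryos at embryonic day 14.5. Embryos of both sexes were pooled. There was 1 group with 2 biological replicates, and no other tissue, age or treatment was included. Each replicate came with a set of peaks, all 150 bp wide, and a set of broader enriched regions called hotspots. Replicate 1 had 260421 peaks on the assembled chromosomes, covering 38.6 Mb or 1.46% of the genome, and replicate 2 had 187973 peaks covering 27.4 Mb or 1.03%. Hotspots numbered 224886 in replicate 1 and 161619 in replicate 2, with median widths of 268 and 229 bp. The median peak signal was 48 in replicate 1 (interquartile range 34 to 74) and 29 in replicate 2 (19 to 49). Read numbers per library were not given in the sources used here, so these peak numbers and signals are the only measure of depth. Coordinates are on mouse build mm10.

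How far the same sites were open in both forebrain samples was examined first. Of the peaks of replicate 1, 47.7% (124185 peaks) overlapped a peak of replicate 2, and of the peaks of replicate 2, 67.5% (126865 peaks) overlapped a peak of replicate 1. When 1 peak set was shifted at random along each chromosome 100 times, the overlap was 2.13% and 3.05% on average, so the observed overlaps were 22.4 and 22.1 times higher and lay above every shift. The shared site with the highest mean rank of signal was a promoter peak 22 bp from a transcription start site (TSS) of Hjurp, which loads the centromeric histone variant, on chromosome 1 from 88277536 to 88277685, with signals of 150 and 147. The promoters of Hnrnpa3, an RNA-binding protein gene (chromosome 2, 75659036 to 75659185, signals 149 and 137), and of Eif4g2, a translation factor gene (chromosome 7, 111083056 to 111083205, signals 150 and 134), followed. All 10 of the strongest shared peaks were promoter peaks, and the others were nearest to Hdac4, Gm49336, Zdhhc5, Tmem60, Fam76a, Ubald2 and Kdm4b.

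Overlap was higher among stronger peaks in both samples. In the lowest signal decile 9.80% of replicate 1 peaks and 20.5% of replicate 2 peaks were shared, and in the highest decile 92.7% and 95.7%. Across the 124185 shared peaks, the signals of both replicates had a Spearman correlation of 0.772 and a Pearson correlation of log2 signal of 0.770, taken across peaks, which are not independent replicates. The signal of a shared peak was higher in replicate 1 by a median ratio of 1.71 (interquartile range 1.30 to 2.29).

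**Figure D1:**
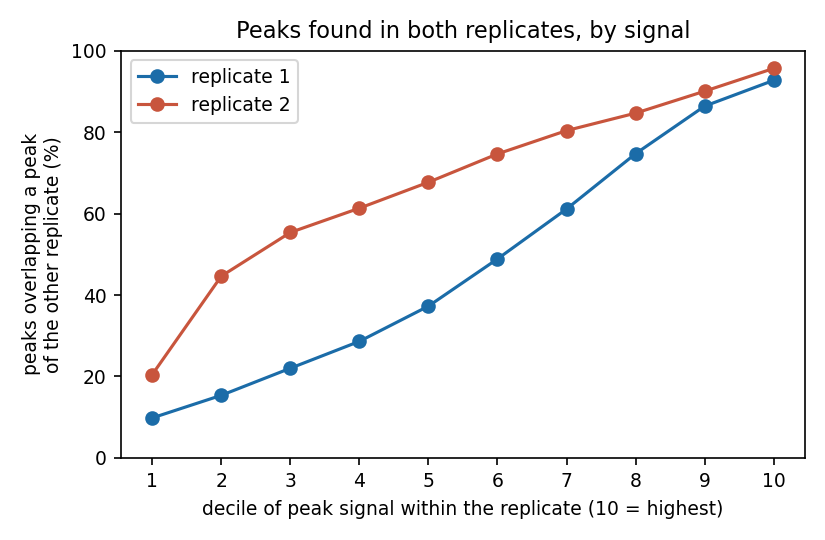
Share of peaks that overlapped a peak of the other replicate (y axis, percent) in each decile of peak signal (x axis, 10 = highest), with 1 line per replicate. The share climbed from 9.80% to 92.7% in replicate 1 and from 20.5% to 95.7% in replicate 2.

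Where the shared sites lay relative to genes was asked next. Of the shared peaks, 24.3% (30145 peaks; Wilson 95% interval 24.0 to 24.5%) lay in promoters, defined as within 1000 bp of a TSS of a protein-coding gene, 4.01% in exons, 31.3% in introns and 40.4% between genes. Shifted peaks fell in promoters in 4.22% of cases, so promoters held 5.76 times more shared peaks than shifted ones, while introns (34.2% of shifted peaks) and intergenic DNA (57.9%) held fewer. Of the 4979 exonic shared peaks, 54.0% touched coding sequence and 34.5% touched untranslated regions without coding bases. The promoter share was 17.4% among all peaks of replicate 1 and 22.0% among all peaks of replicate 2. Promoter peaks were stronger than distal ones in both samples, with median signals of 88 against 66 in replicate 1 and 68 against 32 in replicate 2. The 94040 shared distal peaks lay a median of 28.1 kb from the nearest TSS, and 23.1% lay more than 100 kb away. Chromosome 11 had the most peaks per Mb, 131 in replicate 1 and 105 in replicate 2, and chromosome X had 42.7 and 29.6.

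Whether genes of forebrain cell types carried open promoters more often than other genes was tested with lists of genes fixed in advance. Promoters were open in both samples for all 22 forebrain patterning factors, such as Nr2f1 and Nr2f2, nuclear receptors that pattern the cortex and ganglionic eminences, against 68.4% of other genes. The same was true of all 20 genes of radial glia and neural progenitors, including Sox1 and Sox2, which keep neural progenitors undifferentiated, of all 20 genes of cortical progenitors and glutamatergic neurons, including Pou3f3 and Sox5, and of all 20 genes of the ganglionic eminences and GABAergic neurons, including Foxp1 and Meis2. All 16 diencephalon genes, 20 pan-neuronal genes and 20 housekeeping genes had open promoters as well. Promoters of some lists of other tissues were open less often: 2 of 15 genes of microglia and other leukocytes (13.3%; exact 95% interval 1.66 to 40.5%), 4 of 15 erythroid genes (26.7%; 7.79 to 55.1%), 6 of 20 hepatocyte genes (30%; 11.9 to 54.3%) and 14 of 39 Hox genes (35.9%; 21.2 to 52.8%). This did not hold for choroid plexus (12 of 13) or for meninges and mesenchyme (13 of 15), while muscle had 12 of 19. Of the lists written later, limb bud mesenchyme had 15 of 18 promoters open in replicate 1, hindbrain and spinal cord 18 of 20 and craniofacial mesenchyme 9 of 10. Olfactory receptor genes, the largest mouse gene family of chemosensory receptors, had open promoters in 28 of 1134 cases (2.47%), and vomeronasal receptor genes, which detect pheromones, in 1 of 328 (0.305%).

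By Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 18 lists, 7 lists had open promoters more often than other protein-coding genes and 6 less often. Adjusted p was 0.00117 for the patterning factors, 0.00159 for each of the complete lists of 20 genes and 0.00661 for the diencephalon list. For the lists with fewer open promoters, adjusted p was 9.5e-05 for microglia and leukocytes, 0.00016 for Hox genes, 0.00138 for hepatocytes, 0.0016 for erythroid genes and 1.03e-163 for vomeronasal receptors in the same exact test; for olfactory receptors p was too small to be represented. The remaining 5 lists did not pass the exact test. By the exact test, they were the glial lineage list (11 of 16 genes, adjusted p = 1), choroid plexus (12 of 13, adjusted p = 0.0971), endothelium and pericytes (9 of 17, adjusted p = 0.217), meninges and mesenchyme (13 of 15, adjusted p = 0.202) and muscle (12 of 19, adjusted p = 0.662). Among genes with no promoter peak in either sample were the myelin genes Mag and Mog, the choroid plexus claudin gene Cldn2, the endothelial genes Pecam1 and Eng, the microglial genes Aif1 and C1qb, the erythroid genes Gata1 and Hba-x, the plasma protein genes Ahsg and Ambp, the muscle genes Acta1 and Mybpc3, and Hoxb1 and Hoxb7. The same held for the receptor genes Olfr1, Olfr10, Vmn1r10 and Vmn1r100. By number of genes, the libraries differed most for Hox genes, of which 17 of 39 had an open promoter in replicate 1 and 28 of 39 in replicate 2, so that with replicate 2 alone the share was 71.8% and the exact test was not passed (adjusted p = 1). With a promoter window of 2500 bp the Hox call was also lost (61.5%, adjusted p = 0.187 in the exact test). The erythroid call was lost with replicate 1 alone (46.7%, adjusted p = 0.0587), the diencephalon call within 500 bp (87.5%, adjusted p = 0.131) and among the upper 50% of peaks by signal (adjusted p = 0.0753), all in the same exact test. Calls were gained for meninges and mesenchyme with replicate 1 alone (15 of 15, adjusted p = 0.0131), for choroid plexus with a window of 2500 bp (13 of 13, adjusted p = 0.0356), and for the glial (37.5%, adjusted p = 0.0404), endothelial (35.3%, adjusted p = 0.0248) and muscle lists (36.8%, adjusted p = 0.0213) with fewer open promoters among the upper 50% of peaks by signal, in the exact test. The endothelial share was 82.4% with replicate 1 alone (adjusted p = 0.479 in the exact test). Genes are not independent replicates, and these tests describe the 2 libraries.

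**Figure D2:**
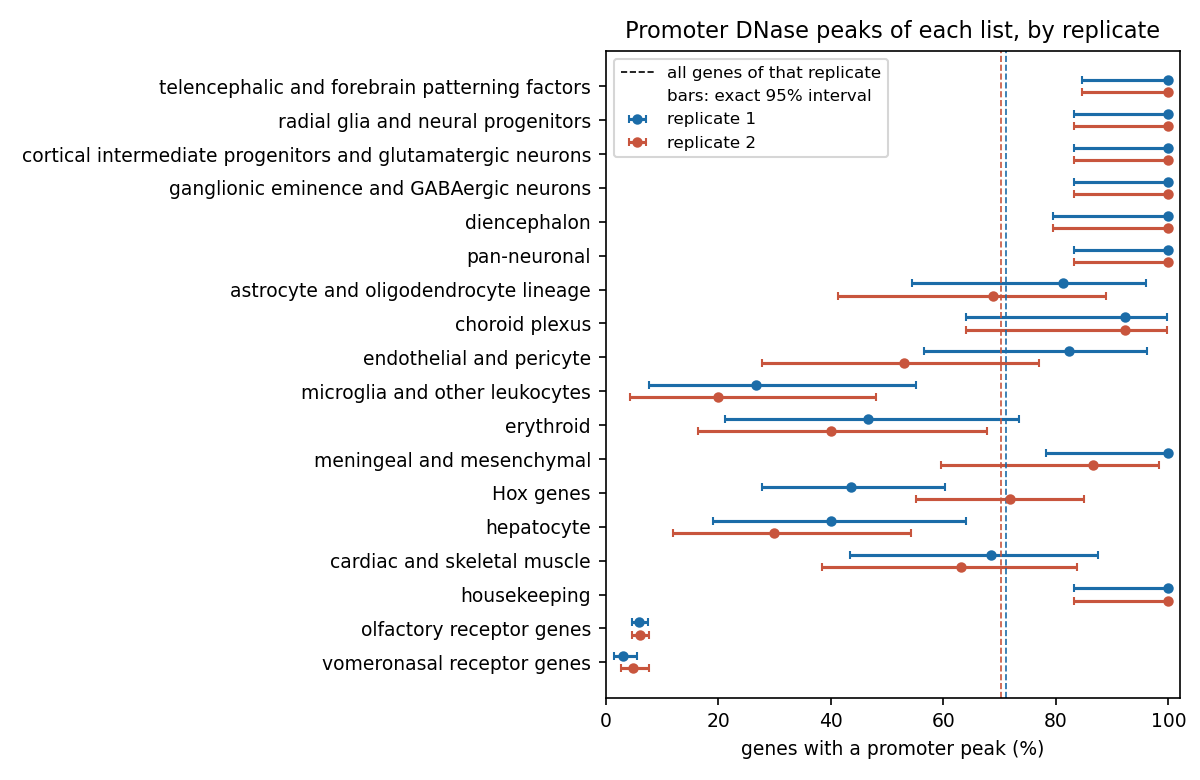
Share of genes of each list with a promoter peak (x axis, percent) in replicate 1 and in replicate 2, with exact 95% intervals, and dashed lines at the share of all protein-coding genes (71.2% and 70.2%). Forebrain and housekeeping lists reached 100% in both replicates, receptor families lay lowest, and Hox genes stood at 43.6% in replicate 1 and 71.8% in replicate 2.

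Distal sites, which include enhancers, were then counted around each gene, in the DNA nearer to any of its TSSs than to those of other protein-coding genes and at most 100 kb away. A gene with many TSSs thus has more such DNA, up to 1565 kb for Pde4d. Genes of cortical progenitors and glutamatergic neurons had 20.4 ± 3.09 shared distal peaks per gene (SE over 20 genes), against a mean of 6.81 in random lists matched on the length of that DNA. Forebrain patterning factors had 17.8 ± 2.47 (22 genes, 3.07 times the mean of random lists), ganglionic eminence and GABAergic genes 16.95 ± 2.85 (20 genes, 2.83 times), radial glia and progenitor genes 15.9 ± 3.31 (20 genes, 2.23 times) and diencephalon genes 14.3 ± 3.06 (16 genes, 2.16 times). Pan-neuronal genes had 15.2 ± 3.05 (20 genes, 1.96 times) and genes of the astrocyte and oligodendrocyte lineage 7.63 ± 1.36 (16 genes, 2.15 times). With 1 replicate left out, all peaks of the other are counted and not only shared ones. By the larger of these counts, each of the 7 lists reached over 1.5 times the numbers above, from 13.2 per gene for the glial lineage to 37.6 for glutamatergic genes. The smaller count did not reach 1.5 times for all lists. Olfactory and vomeronasal receptor genes had 0.183 and 0.0960 times as many distal peaks as random lists.

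Within the lists, Nr2f2 (chromosome 7, 70351944 to 70366735) had 50 shared distal peaks and Nr2f1 had 32. Sox2 (chromosome 3, 34650405 to 34652461) had 60 and Sox1 had 43. Pou3f3, a POU-domain factor of upper-layer cortical neurons (chromosome 1, 42695768 to 42703176), had 62 and Sox5, a factor of deep-layer neurons, had 41. Foxp1 and Meis2, both active in the developing striatum, had 51 and 49. Barhl2 and Tcf7l2, which mark the diencephalon and thalamus, had 48 and 35, and the neuronal genes Rbfox3 and Myt1l had 44 and 43. In the glial list, the myelin gene Mbp had 18 and Olig2, which specifies oligodendrocytes, had 17. Otx2 and Clic6 led the choroid plexus list with 21 and 12, Cdh5 and Pecam1 the endothelial list with 15 and 14, Laptm5 and Ptprc the leukocyte list with 11 and 10, and Tal1 the erythroid list with 6. Twist1 and Col1a1 led the meningeal list with 14 and 12, Foxa1 and Apob the hepatocyte list with 23 and 10, Tbx5 and Ttn the muscle list with 10 each, Ywhaz and Eef1a1 the housekeeping list with 16 and 15, and Hoxa13 the Hox list with 11. Counted in each library separately, Tbx5 had 13 distal peaks in replicate 1 and 39 in replicate 2, and Olig2 had 23 and 47. Of the receptor genes, Olfr1423 had 16, Olfr161 had 8, Vmn1r223 had 13 and Vmn2r86 had 6.

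In a two-sided permutation test with 100000 random lists, adjusted over the 18 lists, the 7 neural lists lay above random lists and both receptor families below them. Random lists were matched on the length of DNA only. The calls therefore do not separate neural genes from developmental regulators of other tissues, which were not tested as a class here. The adjusted p was 7.2e-05 for the patterning, glutamatergic, GABAergic and both receptor lists, from a permutation p of 2.0e-05, the smallest these permutations can give. It was 0.00012 for radial glia, 0.000617 for the diencephalon, 0.00193 for pan-neuronal genes and 0.00848 for the glial lineage in the permutation test. The other 9 lists did not pass the permutation test, with ratios from 0.904 for erythroid genes (adjusted p = 0.936) to 1.63 for housekeeping genes (adjusted p = 0.185). Hox genes were among these (1.33 peaks per gene against 0.891, adjusted p = 0.185), but with replicate 2 alone their ratio was 3.14 (adjusted p = 5.14e-05 in the permutation test), and against random lists not matched on length it was 0.405 (adjusted p = 0.00744 in the permutation test). The glial call was lost when DNA up to 500 kb from the TSS was counted (ratio 1.82, adjusted p = 0.0603 in the permutation test). With 1 TSS per gene, an alternative chosen after seeing the data, the pan-neuronal call was lost (ratio 1.38, adjusted p = 0.185) and housekeeping genes passed (ratio 2.09, adjusted p = 0.0152), while the other 8 calls were kept, in the permutation test. The ratio was then 3.45 for patterning factors, 2.96 for glutamatergic genes, 2.95 for radial glia, 2.68 for GABAergic genes and 2.18 for the diencephalon. How well reads can be placed in the receptor families was not examined.

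**Figure D3:**
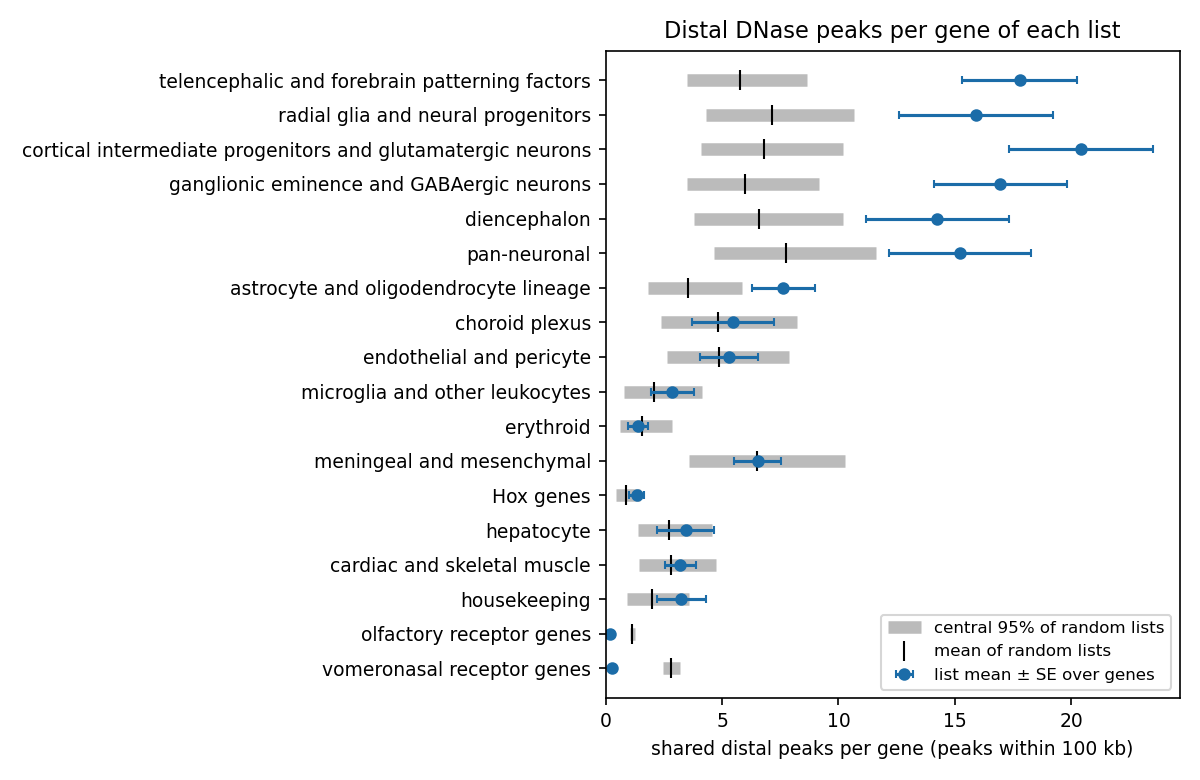
Shared distal peaks per gene (x axis) for each list, as mean ± SE over its genes, with the mean and central 95% of matched random lists in black and grey. The 5 lists of forebrain regions and progenitors lay at 14.3 to 20.4 peaks per gene, to the right of their random ranges.

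Over all 21938 protein-coding genes, the mean was 3.30 shared distal peaks. By raw count, not scaled to the length of DNA per gene, the most were found around Auts2, a neurodevelopmental gene on chromosome 5 from 131437333 to 132543344, and Gse1 on chromosome 8 from 120228456 to 120581390, with 80 each. Mef2c, a transcription factor of developing neurons (chromosome 13, 83504034 to 83667080), had 78, Nfib, a factor of forebrain and glial development (chromosome 4, 82290173 to 82705750), had 69, and the neuronal splicing factor gene Rbfox1 (chromosome 16, 5885355 to 7411526) had 65. Pou3f3, Sox2, Frmd4a, Pde4d and Zfp423 completed the first 10, with 62, 60, 57, 56 and 54. This order depends on the length of DNA counted, from 178 kb for Pou3f3 to 1565 kb for Pde4d, and on the library: Auts2, Rbfox1 and Pde4d had 173, 158 and 152 distal peaks in replicate 1 against 103 for Gse1, and in replicate 2 Gse1 had 135 and Auts2 had 120. With 1 TSS per gene, the shared peaks numbered 9 for Auts2, 30 for Gse1, 14 for Mef2c, 19 for Nfib, 10 for Rbfox1 and 1 for Pde4d. Sox5, Foxp1 and Rbfox3 then had 8 each, whereas Sox2 and Pou3f3 kept their 60 and 62. All 10 genes had promoter peaks in both samples.

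Which transcription factor motifs marked the open sites was tested next, by comparing shared peaks with windows 1000 bp to either side. In distal peaks the motif of CTCF, which anchors chromatin loops, was found in 9.24% of peaks and 0.566% of flanks (odds ratio 17.9, 95% interval 16.7 to 19.2). The RFX motif, bound by factors of ciliated and neural cells, was rare and had an odds ratio of 49.1 (29.8 to 80.8; 484 of 94040 peaks), and the palindrome of NFI factors, which act in neural progenitors and glia, had 40.9 (23.0 to 72.8; 303 peaks). Their order turned in all peaks of replicate 1 (RFX 34.3, NFI 44.4) and of replicate 2 (23.2 and 51.4). Against shuffled sequence the odds ratio was 9.21 (6.43 to 13.2) for NFI and 57.2 (49.1 to 66.7) for CTCF, which was at 11.2 with replicate 1 alone. The E-box of the proneural factors NEUROD and NEUROG was more frequent in distal peaks, at 6.27% against 2.02% (3.24, 3.10 to 3.39). The POU octamer (2.09, 1.95 to 2.24; 1.27 with replicate 2 alone and 3.74 against GC-matched flanks), the LHX/DLX homeodomain motif (1.85, 1.74 to 1.96; 3.85 against GC-matched flanks and 4.42 against shuffled sequence) and the SOX motif (1.23, 1.12 to 1.36) were also more frequent. With replicate 2 alone the LHX/DLX call was lost, as given below. Motifs of MEF2 (0.475), of the blood factors GATA (0.568) and PU.1 (0.877), of the liver factor HNF4 (0.779) and of T-box factors (0.832) were less frequent in distal peaks than in flanks.

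RFX (52.8, 13.02 to 214), NFI (19.2, 2.56 to 143) and CTCF motifs (4.80, 4.09 to 5.64) were more frequent in promoter peaks as well. Against GC-matched flanks RFX rose to 105 (6.51 to 1708) and CTCF to 11.5 (8.67 to 15.3), and NFI was at 13.01 (1.70 to 99.5). The GC box of SP/KLF factors was found in 6.19% of promoter peaks and 0.112% of flanks (odds ratio 58.7, 42.2 to 81.7), and the NFY, NRF1 and ETS motifs had odds ratios of 5.93, 35.8 and 29.6. Against flanks matched on GC content these 4 values were lower, at 4.36 (2.95 to 6.45) for SP/KLF, 5.18 for NFY, 11.7 for NRF1 and 14.1 for ETS. The YY1 motif was found in 95 promoter peaks and in 1 flank. Against unmatched flanks, the NEUROD/NEUROG E-box (1.04) and the POU octamer (1.00) were not more frequent in promoter peaks, and LHX/DLX (0.485) and SOX (0.680) were less frequent.

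By Fisher's exact test, two-sided and adjusted over 21 motifs, 14 motifs were more frequent and 5 less frequent in distal peaks, with HNF4 the weakest of these calls (adjusted p = 0.0127), while YY1 and HNF1 did not pass, though YY1 passed in all peaks of replicate 1 (1.96, adjusted p = 0.0386) and of replicate 2 (2.84, adjusted p = 0.0134). In promoter peaks 9 motifs were more and 8 less frequent in the exact test. With replicate 2 alone, the LHX/DLX call in distal peaks was lost (odds ratio 1.03, adjusted p = 0.343), as were those for T-box factors (0.952, adjusted p = 0.274) and PU.1 (0.998, adjusted p = 1), all in the exact test. With replicate 1 alone the PU.1 call was also lost (0.966, adjusted p = 0.244 in the exact test). Against flanks matched on GC content, the MEF2 odds ratio in distal peaks turned to 1.34, those of LHX/DLX (2.13), SOX (1.30), MEF2 (1.14), AP-1 (1.03) and TEAD (1.24) in promoter peaks turned as well, and the POU octamer (2.95, adjusted p = 1.42e-12) and the NEUROD/NEUROG E-box (1.44, adjusted p = 9.71e-06) passed in promoter peaks in the exact test. The ETS call in distal peaks (1.40, adjusted p = 0.126) and the HNF4 call in promoter peaks (0.689, adjusted p = 0.312) were lost in the exact test. Against shuffled sequence, MEF2 (2.73) and PU.1 (1.30) in distal peaks turned, and the calls for NFY (0.963), AP-1 (1.02) and HNF4 (0.800) were lost.

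**Figure D4:**
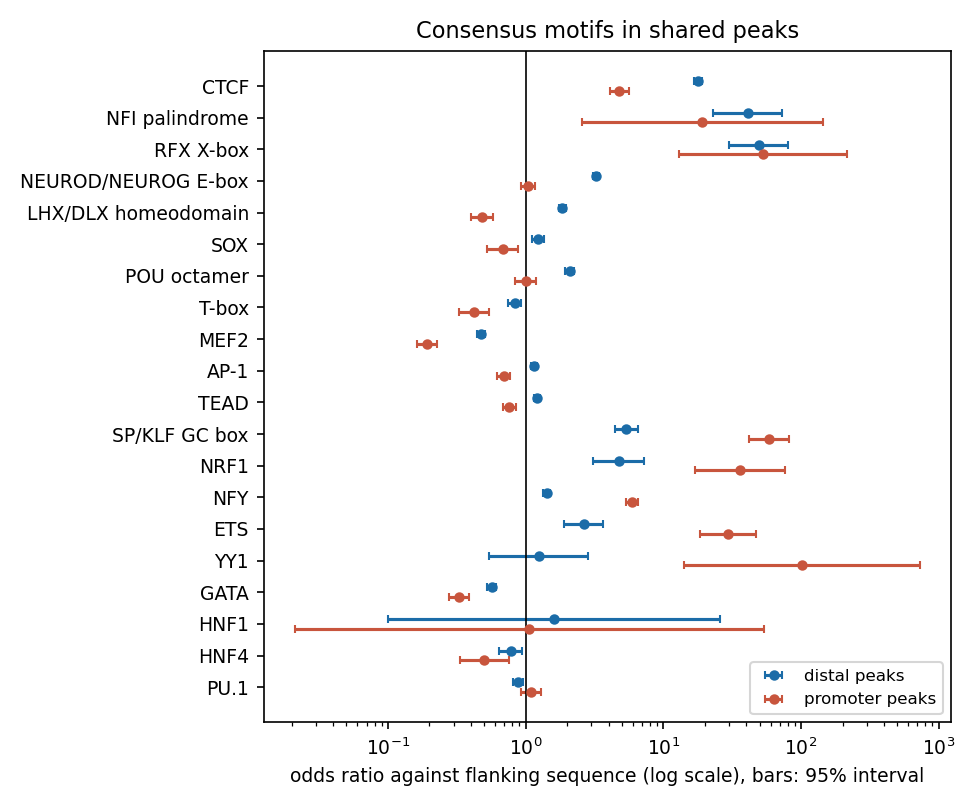
Odds ratio (x axis, log scale) of 20 motifs in shared distal and shared promoter peaks against flanking windows, with 95% intervals. CTCF (17.9), RFX (49.1) and NFI (40.9) lay far above 1 in distal peaks, and the SP/KLF GC box (58.7, or 4.36 against GC-matched flanks, not drawn) in promoter peaks.

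Landmark homeobox loci were compared last. The Dlx genes, which drive interneuron development in the ganglionic eminences, lay in the most densely open of the 6 loci examined, averaged over each locus. The Dlx loci span 18.6 and 18.8 kb, but the Hox clusters 96.8 to 174 kb. Densities are thus averages over unlike spans, and stretches within a Hox cluster may be as dense. The Dlx1-Dlx2 locus (chromosome 2, 71528113 to 71546754) held 33 peaks in replicate 1 and 35 in replicate 2, or 182 ± 7.59 peaks per 100 kb (SD, n = 2), and the Dlx5-Dlx6 locus (chromosome 6, 6863334 to 6882085) held 30 and 31, or 163 ± 3.77. The genome average was 8.47 ± 1.93 peaks per 100 kb. Hotspots covered 99.02% and 89.2% of the bases of Dlx1-Dlx2 and 71.9% and 94.9% of those of Dlx5-Dlx6. Dlx1, Dlx2, Dlx5 and Dlx6 all had promoter peaks in both samples and 11, 21, 17 and 11 shared distal peaks.

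The Hox clusters, which pattern the hindbrain, trunk and limbs, differed between both libraries. HoxA, on chromosome 6, held 30 peaks in replicate 1 and 100 in replicate 2, of which 21 of the replicate 1 peaks were shared, or 61.7 ± 47.0 per 100 kb (SD, n = 2). HoxD (chromosome 2, 74668310 to 74765142) held 9 and 56 peaks, 7 of them shared, or 33.6 ± 34.3 per 100 kb. HoxB (chromosome 11, 96194316 to 96368256) held 22 and 35 peaks (16.4 ± 5.28 per 100 kb) and HoxC (chromosome 15, 102921103 to 103036852) held 13 and 19 (13.8 ± 3.67 per 100 kb). Promoters were open for 3 of the 9 HoxD genes in replicate 1 and for 6 in replicate 2. Relative to its own genome average, HoxD was at 0.945 in replicate 1 and 8.15 in replicate 2, and HoxA at 2.90 and 13.4. Hotspots covered 2.45% and 2.48% of the bases of HoxC, 0.899 times the genome average over both replicates, while its peak density was 1.73 times the average. The SD between the replicates exceeded the mean for HoxD, and no test was possible with 2 libraries.

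**Figure D5:**
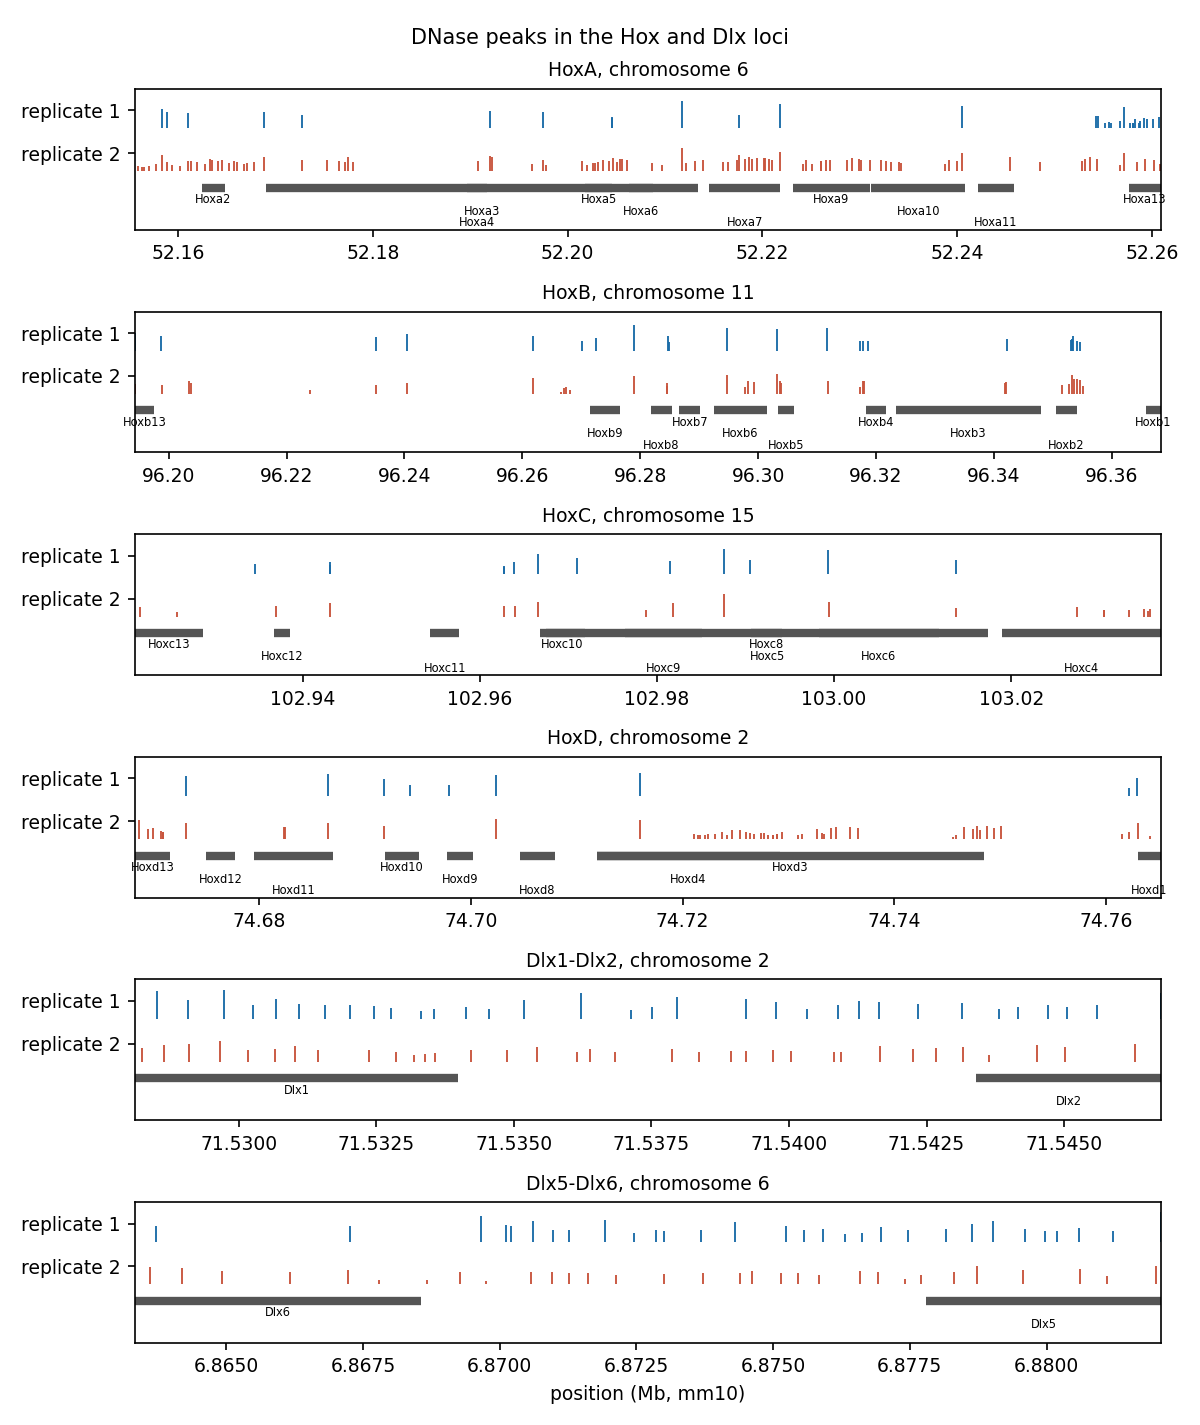
Positions of peaks (x axis, Mb on mm10) in the Hox clusters and Dlx loci, with line height proportional to peak signal and genes as grey bars. Replicates had similar numbers of peaks in the Dlx loci (33 and 35, 30 and 31), whereas replicate 2 had 100 peaks against 30 in HoxA and 56 against 9 in HoxD. Replicate 2 had fewer peaks over the genome, and relative to each replicate's genome average every locus shown was higher in replicate 2.

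Peaks found in 1 sample only were weaker than shared ones. Replicate 1 had 136236 such peaks (52.3%) with a median signal of 37, against 70 for its shared peaks, and replicate 2 had 61108 (32.5%) with a median of 20, against 36. Promoters held 15162 of the peaks of replicate 1 only (11.1%) and 11029 of those of replicate 2 only (18.05%), against 24.3% of shared peaks. Of the peaks of replicate 1 only, 12.9% lay in hotspots of replicate 2, and of those of replicate 2 only, 31.8% lay in hotspots of replicate 1. Mean GC content was 45.4% (SD 6.92) in distal peaks of replicate 1 only, 49.6% (SD 6.08) in those of replicate 2 only and 50.4% (SD 6.86) in shared distal peaks. Some motifs were unequally divided: the LHX/DLX motif was in 4.09% of distal peaks of replicate 1 only and in 0.829% of those of replicate 2 only, and the NEUROD/NEUROG E-box in 6.18% and 2.60%. The CTCF motif was in 1.55% and 1.61%. These values compare 1 library with 1 other, and peaks are not replicates.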

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

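The peaks outside the assembled chromosomes are a signal in data that no comparison of the report uses. There were 208 of them in replicate 1, of which 29 lay on the mitochondrial genome and 179 on unplaced scaffolds. In replicate 2 there were 188 such peaks, of which 27 lay on the mitochondrial genome and 161 on unplaced scaffolds. No biological explanation was tested for these peaks.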

How the results depend on the processing

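The values without each replicate for the genomic distribution and for the loci, and those with 1 TSS per gene, were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because there was only 1 group. Of 357 alternative values with a test, 299 kept their direction and their side of the threshold, 14 fell short of it, 10 newly passed it and 34 changed direction. For the values below, the cause was not tested, apart from changes that follow from a setting itself. A wider promoter window or more TSSs can only raise the promoter share, and a stricter overlap can only lower the shared share. Keeping the upper 50% of shared peaks by rank of signal narrows the range of signals, which tends to lower a correlation. By construction, the upper 50% of peaks by signal numbered 130210 in replicate 1 and 93986 in replicate 2. The shared share of replicate 1 was 38.7% with an overlap of 50%, 60.3% with equal numbers, 56.4% among the upper 50% by signal and 50.7% for hotspots, and that of replicate 2 was 54.2%, 61.7%, 78.5% and 75.9%. Spearman's correlation across peaks was 0.793 with an overlap of 50% and 0.572 among the upper 50%. The promoter share was 19.1% within 500 bp, 31.1% within 2500 bp, 28.3% with TSSs of all genes, 32.6% among the upper 50% and 17.4 to 22.0% without either replicate. Peaks of 1 replicate only that also lay outside the other's hotspots made up 45.6% and 22.2%. The promoter share of the glial list turned at 62.5% within 500 bp, 68.75% with hotspots and without replicate 1 (68.75 to 81.25% without either), and 37.5% among the upper 50%. That of endothelial genes turned at 82.4% without replicate 2 (52.9 to 82.4%), of Hox genes at 71.8% without replicate 1 (43.6 to 71.8% without either) and of muscle at 78.9% within 2500 bp. Distal peaks per gene moved also for called lists: without replicate 1 and without replicate 2, they numbered 29.1 and 37.6 for glutamatergic genes, 33.3 and 29.9 for patterning factors, 27.8 and 32.2 for GABAergic genes, 25.1 and 28.8 for radial glia, 30.2 and 26.8 for the diencephalon, 21.5 and 35.4 for pan-neuronal genes and 12.4 and 13.2 for the glial lineage. Against unmatched random lists the ratio was 6.18 for glutamatergic genes, 5.38 for patterning factors, 5.15 for GABAergic genes, 4.82 for radial glia, 4.61 for pan-neuronal genes and 4.33 for the diencephalon. With 1 TSS per gene the pan-neuronal ratio fell to 1.38 and the call was lost, and housekeeping genes passed at 2.09. Ratios of distal peaks that turned were all of lists not called: choroid plexus 0.975 (50 kb) and 0.990 (50% overlap), endothelium 0.979 (without replicate 2; 0.979 to 1.12 without either), erythroid 1.07 (without replicate 1), 1.005 (without replicate 2) and 1.02 (50% overlap), meninges 0.875 (500 kb), 0.989 (without replicate 2; 0.989 to 1.54), 0.957 (50% overlap) and 0.841 (upper 50%), hepatocytes 0.857 (upper 50%) and muscle 0.964 (without replicate 2; 0.964 to 1.77). Against unmatched random lists, microglia turned to 0.871, Hox to 0.405, muscle to 0.976 and housekeeping to 0.987. The motifs less frequent in distal peaks numbered 5, but 2 against shuffled sequence and 3 to 4 without either replicate, and in promoter peaks 8, but 2 against GC-matched flanks. In distal peaks, NFI was at 9.21 and CTCF at 57.2 (shuffled), MEF2 turned to 1.34 (GC-matched) and 2.73 (shuffled), NFY to 0.963 and PU.1 to 1.30 (shuffled), YY1 to 0.636 (GC-matched) and HNF1 to 0.564 (without replicate 2; 0.564 to 1.58). In promoter peaks, GC-matched odds ratios turned to 2.13 for LHX/DLX, 1.30 for SOX, 1.14 for MEF2, 1.03 for AP-1 and 1.24 for TEAD. By bases inside hotspots, HoxC was at 0.899 of the genome average, Dlx1-Dlx2 at 34.0 and Dlx5-Dlx6 at 31.1, and by peaks HoxD was at 0.945 without replicate 2 (0.945 to 8.15 without either). Read depth was not given in the sources used here, so the absence of a weak peak from 1 library means only that it was not detected there.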

Other observations

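The test of depth for the Hox clusters was chosen only after its result was seen, and the other tests here were chosen after both libraries had been seen to differ at Hox genes and motifs, the comparisons with CpG islands and transcription factor families after the first of them. The readings of some tests were changed after their values were seen. By the limits written before the tests, hindbrain or spinal cord tissue and limb tissue beyond other transcription factor genes would have been read as ruled out. The same holds for less forebrain chromatin in replicate 2, a replicate 2 with no forebrain, GC content at the Hox clusters and weak peaks near the threshold. All are given here as open. The comparison of forebrain factor genes with other factor genes was added last. Distal peaks were counted around every TSS, so long genes have more DNA. The 4 genes with the largest excess of distal peaks of replicate 1 only over those of replicate 2 only were Rbfox1, a splicing factor gene of neurons (93 and 16), Pde4d, a phosphodiesterase gene (96 and 20), Tenm2, a synaptic adhesion gene (85 and 10), and Dlg2, a synaptic scaffold gene (75 and 8). The pan-neuronal list had 403 and 122, a log2 lean of -0.70 after scaling to all genes, at percentile 14.65 of random lists.

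The 4 genes with the largest excess of distal peaks of replicate 2 only were Hand2, which acts in heart, limb and sympathetic neurons (54, and 0 of replicate 1 only), Pax3, a factor of dorsal neural tube and neural crest (42 and 5), Tfap2a, a neural crest factor (39 and 2), and Prdm16, a factor of neural progenitors and brown fat (57 and 23). The 257 genes of developmental transcription factor families together leaned to replicate 2 by a log2 ratio of 1.37. The lean was -0.36 in the decile of genes with the fewest CpG islands nearby and 1.46 in the decile with the most. Hox genes had 124 distal peaks of replicate 2 only and 31 of replicate 1 only (percentile 99.99 of random lists). Of the other 17 lists, those that leaned to replicate 2 beyond the limit set were vomeronasal receptors (log2 lean 1.62, percentile 100), forebrain patterning factors (1.34, 100), the diencephalon (1.38, 99.96), muscle (2.06, 99.94), meninges (1.26, 99.85), choroid plexus (1.16, 98.77) and radial glia (0.51, 97.57).

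Replicate 2 had more peaks in HoxA and HoxD, and no biological explanation other than tissue content was tested, as both samples belong to 1 group. By the ratio of replicate 2 to replicate 1 peaks, the lower of both clusters lay at percentile 99.7 of 9515 windows, and at 99.8 among windows of like GC content. HoxB was at 97.7 and 96.9, and HoxC at 96.4 and 95.3. HoxA and HoxD were chosen for this ratio after it was seen, so these percentiles do not decide on depth or GC content as the cause. All 5 forebrain lists passed with replicate 2 alone. The random lists were matched on length only and do not tell forebrain genes from other factor genes, so this does not decide whether replicate 2 held forebrain. Other tissue in replicate 2 remains a hypothesis: lists of limb bud mesenchyme (152 distal peaks of replicate 1 only, 225 of replicate 2 only), hindbrain and spinal cord (115 and 263) and craniofacial mesenchyme (41 and 166), which share 0 genes with the other lists, leaned to replicate 2 at percentiles 100, 100 and 99.98, the limb list still at 99.69 after matching on CpG islands, with Tbx2 at 1 and 21 distal peaks, shared ones included, but Shox2 at 28 and 15, and promoters already open in replicate 1 for 15 of 18, 18 of 20 and 9 of 10 genes. Against other transcription factor genes, however, the limb list was at percentile 69.52, the hindbrain list at 97.26, too close to the limit set for the test to decide, and the craniofacial list at 99.57. For limb tissue this comparison cannot decide either. The limb list also holds genes outside these families, such as Col2a1 and Acan. The other factor genes include Tbx5, a limb factor left out of that list, beside factors of other tissues. Much of the limb lean came from Hand2, with 0 distal peaks of replicate 1 only and 54 of replicate 2 only, and Lmx1b, with 5 and 37. In the limb list 12 of 18 genes leaned to replicate 2. Its lean without Hand2 and Lmx1b was not tested. Recovery of DNA rich in CpG islands may also contribute and stays open, because both clusters were at percentile 100 but only 2 and 7 windows had like island cover, and a sequencing batch cannot be told apart from the replicate.

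The LHX/DLX motif was more frequent in distal peaks of replicate 1 only than in those of replicate 2 only (odds ratio 5.11, 4.62 to 5.65 over peaks, which does not cover the spread between replicates), as were the NEUROD/NEUROG (2.47, 2.33 to 2.63), POU (3.72, 3.34 to 4.15), RFX (7.05, 4.71 to 10.6) and MEF2 motifs (3.62, 3.25 to 4.04; 2.09 after GC matching) and, less so, SOX (0.808% and 0.665%), AP-1 (3.36% and 2.93%) and TEAD (3.17% and 2.92%), but not CTCF (0.965, 0.888 to 1.05), NFI after GC matching (1.30, 0.929 to 1.82) or T-box (0.626% and 0.779%). For LHX/DLX, the tables argue against GC content (3.28, 2.93 to 3.66 after matching) and against CpG content (5.23, 4.50 to 6.07 in peaks with at most 1 CpG) as the whole cause. In the upper 50% by signal of each set, the odds ratio was 5.53 (4.83 to 6.33). That split was made within each replicate, on a signal not stated to be scaled to depth. Median signals over all peaks of 1 replicate only were 37 in replicate 1 and 20 in replicate 2. The split therefore does not decide on weak peaks near the threshold. Less forebrain chromatin in replicate 2 is a candidate explanation that stays open: the 98 genes of the 5 forebrain lists leaned to replicate 2 against random lists (percentile 100) and after matching on CpG islands (97.44), the opposite of what it needs, but these comparisons did not allow for the lean of transcription factor genes as a class. The 53 of these genes that belong to transcription factor families leaned to replicate 2 less than the other 204 genes of these families (log2 ratio 0.79 against a median of 1.67, percentile 0.06), as it needs, although more of other tissue would give the same. Of the whole lists, radial glia, glutamatergic and GABAergic genes were low (percentiles 1.84, 0 and 0.99) but patterning factors and the diencephalon near the middle (44.74 and 49.37). Whole lists also hold genes outside these families, in differing shares, so their percentiles do not decide. No biological explanation other than tissue content was tested.

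Whether motifs differed between shared distal peaks near ganglionic eminence and GABAergic genes and those near glutamatergic genes could not be decided. The LHX/DLX motif was in 6 of 339 shared distal peaks near ganglionic eminence genes and in 16 of 408 near glutamatergic genes (odds ratio 0.441, 0.171 to 1.14, Fisher's exact p = 0.126, adjusted 0.253). The NEUROD/NEUROG E-box was in 21 of 408 peaks near glutamatergic and 16 of 339 near ganglionic eminence genes (odds ratio 1.10, 0.562 to 2.13, Fisher's exact p = 0.866). Too few peaks held either motif for a difference of this size to be told from none.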
